A study of Mus musculus with 22 samples.

How the data were processed

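RNA extracted with RNeasy from 11 mouse pancreatic cell lines, 2 arrays per line, was hybridised to Affymetrix Gene ST arrays, per the labels. The deposited table holds log2 values after RMA (background correction, quantile normalization and probe summary), which the authors made with Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes. RMA tends to compress large differences, and the scale was not calibrated here. The genome build of the array annotation is not given in the sources used here, so no positions are printed. The values of the 22 arrays were used as deposited.

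Of 35556 probe sets, 21789 were assigned to 1 gene symbol by the array's annotation, 1621 to several and 12146 to none, and the last 2 kinds were left out. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes. Symbols were checked against a reference gene table, where 21698 of the Entrez identifiers were found and 0 symbols needed an update. Probe sets that carry Kras, Trp53 or Pten were not analysed here.

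The unit of the comparisons was the cell line, represented by the mean of its 2 arrays, because arrays of the same line are not independent samples of a model. Line means were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with the 11 lines sharing 1 estimate of the spread between lines. The contrasts were Kras against p53, Kras against Pten, Pten against p53, and Tsc1 fl/fl against Tsc1 fl/+ within the p53 model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. SE is the moderated standard error of the difference. Differences among lines of a model were tested with limma's moderated F over all 22 arrays, whose spread is that between duplicates, and each Kras line was set against the mean of the other 3 in the same fit. The sum of squares of each gene was split between models, lines and duplicates without a test. Input was read with the data.table package, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

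The groups, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. There were 24 lists with 520 entries, of which 483 were measured: ERK pathway output, p53 target genes, FOXO target genes, glycolysis and HIF1A targets, sterol and fatty acid synthesis, ATF4 and amino acid response, mTOR pathway components, lysosome and TFEB targets, ribosome biogenesis, proliferation, interferon response, NRF2 target genes, matrix proteases and invasion, classical and quasi-mesenchymal PDAC (pancreatic ductal adenocarcinoma) subtypes, Y-linked genes with Xist, and markers of epithelial, mesenchymal, fibroblast and stellate, acinar, ductal, endocrine, endothelial and leukocyte cells. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists of a comparison, and again with an estimated correlation and with fry. Named genes were the engineered or commonly lost genes Kras, Trp53, Pten, Tsc1, Tsc2, Cdkn2a, Cdkn2b and Smad4. The 10 largest changes in each direction among called genes whose groups did not overlap were also named, gene models without a proper name, Y-linked genes and Xist apart. From each list the 4 members with the largest absolute change were eligible, and for each Kras line the 5 highest and 5 lowest genes.

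The procedure was tested on simulated data, drawn as independent normal noise around each gene's mean with that gene's residual spread between lines, with known shifts added. Of 100 genes shifted by a log2 value of 1, the tests called 75 for Kras against p53, 63 for Kras against Pten, 78 for Pten against p53 and 59 within the p53 model. At a shift of 2 they called 97, 93, 88 and 89. Among the 19938 genes, 12, 7, 11 and 8 unshifted genes were called. A list shifted by 0.5 was called in all 4 comparisons, with 0 other lists called by camera, in data where genes are independent, unlike real arrays. For line tests, 99 of 100 genes shifted by 1 were called for 897 and 96 by the F test, with 12 and 15 false calls.

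Alternatives to the fit on line means were arrays with the line as a random block, the same with a replicate block as a further choice, arrays as independent replicates, only the lines of the groups compared, renewed quantile normalization, median centring, the upper 50% of genes by level, the mean of a gene's probe sets, eBayes with trend and robust options, a minimum absolute log2 fold change of 1, 946 and 946F averaged, the p53 side restricted to Tsc1 fl/+ lines, and each line left out in turn. Chosen after the values were seen were the first array of 952 alone, the proliferation mean as a covariate, and 926 and 928 left out together. Other divisions of the lines into groups of the same sizes were run, 35 for each comparison of models and 3 within the p53 model.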

Results

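Gene expression was measured on 22 arrays carrying RNA from 11 cell lines grown from the pancreas of genetically engineered mice of mixed strain. Each line was measured on 2 arrays, which the labels call biological replicates. In every model Cre was driven by P48, a gene of pancreatic progenitors. The labels name 3 models and assign each a route to mTOR, the kinase complex that couples growth to nutrients and that the Tsc1 protein restrains. The p53 model (p53-mTOR) had 4 lines, all labelled P53 fl/fl, so that p53 itself was targeted in them. Of these, 911 and 961 were labelled Tsc1 fl/+ from histologically normal pancreas and 946 and 946F were labelled Tsc1 fl/fl from acinar carcinoma. The Kras model (Kras/Erk-mTOR) carried an activated Kras allele and had 4 Tsc1 fl/+ lines from ductal adenocarcinoma, 897, 399, 403 and 907. The Pten model (PI3K/Akt-mTOR) had 3 Pten fl/fl, Tsc1 fl/+ lines from cystic lesions, 926, 928 and 952. Array medians lay between 7.53 and 7.80 on the log2 scale. They follow quantile normalization within RMA and do not measure the amount of RNA hybridised. The number of arrays limits the precision of every value. The second array of 952 had the highest median, 7.80, and the narrowest spread, an SD of 2.22. The p-values of the comparisons between groups measure the spread between lines, not between duplicates. Model went with histology throughout, and within the p53 model genotype went with histology, so these cannot be told apart. No overlap or correlation between comparisons that share lines was calculated.

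Each line's nearest neighbour belonged to its own model, although not every line of a model was closer than lines of other models. Pearson correlations across the 19938 genes had a median of 0.997 between duplicates (0.991 to 0.999 over 11 lines, genes being no independent replicates), 0.978 between lines of the same model (60 pairs of arrays, 0.955 to 0.992) and 0.954 between models (160 pairs, 0.931 to 0.970). Over all probe sets the duplicates of 952 correlated at 0.986, below those of the other lines, at 0.991 to 0.997. The weakest nearest-neighbour link was that of 952 with 928, at 0.969, and 928 correlated with the p53 line 946F at 0.971. Differences between models held 50.4% of the sum of squares over all genes, differences between lines of a model 44.3% and differences between duplicates 5.29%. The median mean squares were 0.141, 0.0613 and 0.0142.

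**Figure D1:**
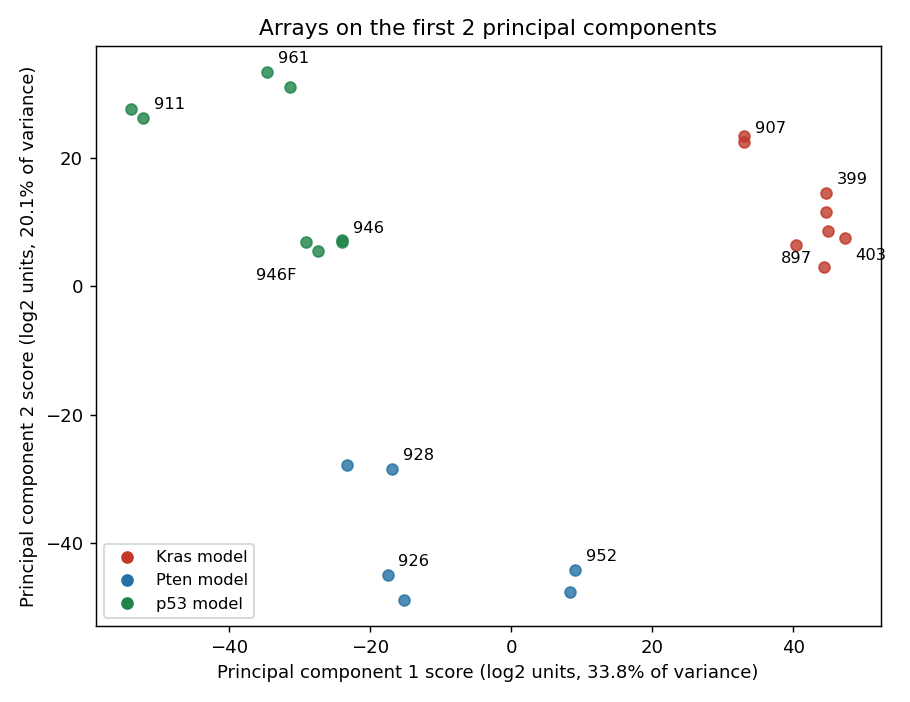
Scores of the 22 arrays on the first and second principal components of the log2 values, with each array as a point coloured by model. The first axis holds 33.8% of the variance and the second 20.1%, and the arrays of a model lie in the same part of the plot, with 952 apart from 926 and 928 on the first axis (9.08 and 8.30 against -23.3 to -15.1).

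The labels were checked on the targeted gene before the comparisons. Tsc1 transcript lay between 9.19 and 9.62 in the 9 lines labelled Tsc1 fl/+ (mean 9.39, SD 0.13). The line labelled 946 had 8.31, below all of them, while the line labelled 946F had 9.98, above all of them. The difference between 946F and 946 was 1.66 (SE 0.09 from duplicates, n = 2 arrays each, limma adjusted p = 2.08e-09). Between the lines labelled Tsc1 fl/fl and the lines labelled Tsc1 fl/+ of the p53 model, the Tsc1 difference was -0.16 (SE 0.40, adjusted p = 1). Probes outside the deleted part of a gene check nothing, and the positions of the probes were not used here. Tsc2, the partner of Tsc1, lay between 11.08 and 11.40 in all lines, and Smad4 between 11.65 and 12.23. Probe sets for Kras, Trp53 and Pten were not analysed here.

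The Cdkn2a and Cdkn2b genes, neighbours that encode cell cycle inhibitors often lost in pancreatic cancer, differed widely. Cdkn2a had a level of 10.05 to 11.46 in the p53 lines and 7.39 to 8.19 in the Kras lines. The Pten lines spanned 7.90 in 952, 9.17 in 928 and 10.01 in 926. Cdkn2b had 10.37 to 11.40 in the p53 lines, 7.79 in 399 and 7.99 in 907, but 10.09 in 897.

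**Figure D2:**
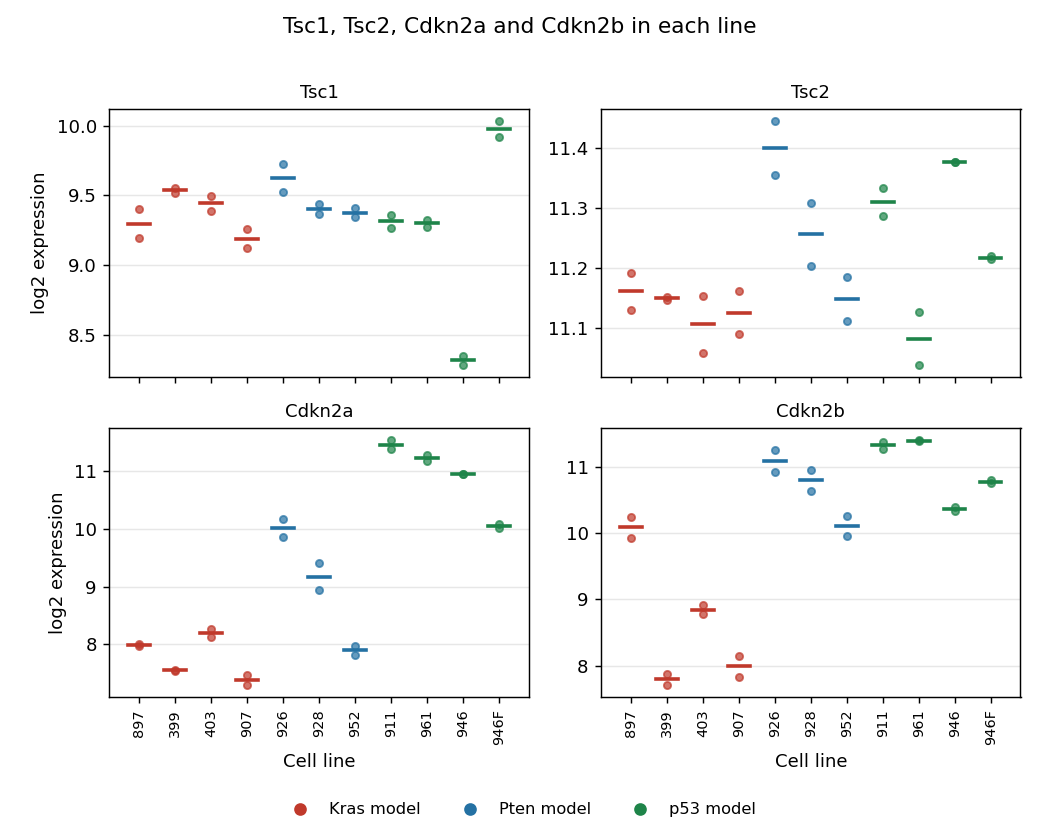
Log2 levels of Tsc1, Tsc2, Cdkn2a and Cdkn2b in the 11 lines, with points for arrays, bars for line means and colours for models. Tsc1 is lowest in 946, at 8.31, and highest in 946F, at 9.98.

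The comparison of Kras with p53 lines asks how tumour lines driven through Kras and Erk differ in transcription from the p53 lines, of which 911 and 961 came from histologically normal pancreas. Cdh17, an intestinal cadherin, was higher by a log2 fold change of 5.78 (SE 0.41, n = 4 and 4 lines, adjusted p = 7.11e-05). Il1a, the cytokine interleukin 1 alpha, was higher by 4.97 (SE 0.42), Tns4, a tensin of focal adhesions, by 4.88 (SE 0.40), Wfdc2 by 4.79 (SE 0.35) and the retinaldehyde dehydrogenase Aldh1a3 by 3.69 (SE 0.24). Cd53, Gabrp, St3gal6, Mall and Tc2n followed, between 3.72 and 4.21. Postn, which encodes periostin, changed by -6.25 (SE 1.22, adjusted p = 0.00872), the collagen cross-linking enzyme Lox by -6.12 (SE 1.06), the smooth muscle actin Acta2 by -4.64 (SE 0.83), the gelatinase Mmp2 by -4.51 (SE 0.78) and the small chaperone Hspb8 by -4.41 (SE 0.24, adjusted p = 4.73e-05). Ogn, Dpt, Ccdc80 and Peg3 changed by -5.06 to -4.56, and Dcn, which encodes decorin, by -5.04 (SE 1.38). The Dcn call was lost on leaving out 911, 961, 946, 897, 399, 403 or 907, with adjusted p from 0.0742 to 0.0933. Cdkn2a fell by 3.14 (SE 0.44, adjusted p = 0.00173) and Cdkn2b by 2.29 (SE 0.47, adjusted p = 0.0108). In all, 1274 genes were higher and 1381 lower of 19938 tested by limma. Over all genes tested, 20.9% had all lines of 1 group above all lines of the other, an arrangement that chance gives to 2.86%. Leaving out 403 lowered the number called from 2655 to 1634.

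Of 20 measured transcripts of ERK pathway output, which read the activity of the kinase downstream of Kras, 12 rose in the Kras lines against the p53 lines and 8 did not pass (camera adjusted p = 2.25e-08, adjusted p = 0.202 with an estimated correlation), with 16 higher and 1 lower when adjusted over the list alone. The feedback inhibitor Spry4 rose by 2.02 (SE 0.21), the ERK phosphatase Dusp6 by 1.78 (SE 0.26) and Ier3 by 1.66 (SE 0.22), while Etv1 had 1.73 (SE 0.69, adjusted p = 0.139). Of 25 transcripts of glycolysis and HIF1A targets, 19 rose and 6 did not pass (camera adjusted p = 2.08e-12, adjusted p = 0.0884 with an estimated correlation), and 19 were higher and 1 lower adjusted over the list alone. They included the hypoxia sensor Egln3 at 3.08 (SE 0.38), the aldolase Aldoc at 2.66 (SE 0.35) and the lactate exporter Slc16a3 at 2.47 (SE 0.34). Of 23 p53 target genes, 9 rose, 1 fell and 13 did not pass (camera adjusted p = 0.000183, adjusted p = 0.0884 with an estimated correlation), and 11 were higher and 1 lower adjusted over the list alone. The death receptor Fas fell by 1.92 (SE 0.19), and the DNA polymerase Polk rose by 1.35 (SE 0.09). Of 22 lysosome and TFEB targets, 1 rose, 6 fell and 15 did not pass (camera adjusted p = 0.0095, adjusted p = 0.565 with an estimated correlation), and 2 were higher and 7 lower adjusted over the list alone. Of 23 ribosome biogenesis genes, 1 rose, 2 fell and 20 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.697 with an estimated correlation), with Bop1 down by -1.02 (SE 0.17). The lysosome call was lost without 946 (adjusted p = 0.0570), and the ribosome call without 946 (0.0944), 897 (0.167) or 403 (0.0514). Among the upper 50% of genes by level both calls were lost (0.0851 and 0.119), and the lysosome call was also lost with 946 and 946F averaged (0.0510) or the p53 side restricted to Tsc1 fl/+ lines (0.567).

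Cell identity lists were tested in the same way for Kras against p53 lines. Of 28 epithelial genes, 6 rose, 1 fell and 21 did not pass (camera adjusted p = 0.000136, adjusted p = 0.434 with an estimated correlation), and 8 were higher and 1 lower adjusted over the list alone. The epithelial mean was lowest in 911 (8.41) and 961 (8.64), while 946 (9.69) lay above the Kras lines 399 (9.63) and 403 (9.60). The keratin Krt7 rose by 3.23 (SE 0.32) and the placental cadherin Cdh3 fell, from a mean of 10.92 to 7.93. Of 17 ductal genes, 4 rose and 13 did not pass (camera adjusted p = 0.00133, adjusted p = 0.202 with an estimated correlation), and 7 were higher adjusted over the list alone. Of 20 classical PDAC subtype genes, 5 rose, 1 fell and 14 did not pass (camera adjusted p = 0.00173, adjusted p = 0.350 with an estimated correlation), and 8 were higher and 1 lower adjusted over the list alone, with the adhesion molecule Ceacam1 at 3.68 (SE 0.54) and the galectin Lgals4 at 3.09 (SE 0.59). Of 18 fibroblast and stellate genes, 6 fell and 12 did not pass (camera adjusted p = 0.000136, adjusted p = 0.434 with an estimated correlation), and 7 were lower adjusted over the list alone. Of 17 mesenchymal transition genes, 4 fell and 13 did not pass (camera adjusted p = 0.000981, adjusted p = 0.530 with an estimated correlation), and 5 were lower adjusted over the list alone, with the matrix protein Sparc at -3.93 (SE 0.72) and Tgfbi at -3.05 (SE 0.61). Quasi-mesenchymal PDAC subtype genes were not called (camera adjusted p = 0.0691), with 5 of 18 higher and 1 lower, also adjusted over the list alone. They were called up with arrays and the line as a random block (0.0453), without 911 (0.0318) or 946 (0.0238), after renewed quantile normalization (0.0392), with 946 and 946F averaged (0.0471), against the Tsc1 fl/+ lines alone (0.0363) and by fry (0.00347). Sterol and fatty acid synthesis, ATF4, proliferation, interferon and NRF2 lists were not called, with camera adjusted p of 0.0906, 0.595, 0.165, 0.512 and 0.265. Leaving out a line gave a call in some of them, down for sterol genes without 911 (0.0326), 946F (0.0230) or 897 (0.0283) and for proliferation without 907 (0.0136), and up for interferon genes without 961 (0.0215) and NRF2 targets without 946 (0.0451). NRF2 targets were also called up against the Tsc1 fl/+ lines alone (0.0114). The members of the ATF4 list had a median of -0.07, a mean of 0.03 and a test that pointed down.

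The comparison of Kras with Pten lines asks how the Kras/Erk route differs from the PI3K/Akt route. Tns4 was higher in the Kras lines by 5.51 (SE 0.43, n = 4 and 3 lines, adjusted p = 0.000318), Il1a by 4.78 (SE 0.46), Aldh1a3 by 3.81 (SE 0.26) and the ectonucleotidase Nt5e by 3.67 (SE 0.58). Gatm, an enzyme of creatine synthesis, was higher by 4.87 (SE 0.95, adjusted p = 0.0139), and St3gal6, Klhl1, Ceacam1, Slc9a2 and Avil by 3.44 to 3.75. The receptor Fgfr2 was lower at -4.12 (SE 0.37, adjusted p = 0.000455), the esterase Aadac at -4.13 (SE 0.46), the fibrillar collagen partner Col12a1 at -4.35 (SE 0.63) and the stem cell marker Olfm4 at -3.76 (SE 0.68). Vgll3, Gria3 and Pamr1 had -4.04 to -3.72. The call of Habp2 (-4.10) was lost without 399, 403, 907, 926 or 952 (adjusted p from 0.0540 to 0.0809), that of Ccdc80 (-3.99) without 926 (0.0516) or 928 (0.0509), and that of Gsta3 (-3.89) without 403 (0.0517), 926 (0.0700) or 952 (0.0569). Cdkn2a had -1.25 (SE 0.47, adjusted p = 0.142) and Cdkn2b -1.99 (SE 0.51, adjusted p = 0.0401). The Cdkn2b call was lost without any of 9 lines, the exceptions being 946 and 897, with adjusted p from 0.0501 to 0.134. In all, 812 genes were higher and 847 lower, or 48.9% higher, against 69.9% higher once each array was centred on its median. Over all genes tested, 21.4% had all lines of 1 group above the other, which chance gives to 5.71%. The number called was 923 without 399, 913 without 403, 981 without 907 and 855 without 926.

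Of 25 sterol and fatty acid synthesis genes, 15 rose in the Kras lines and 10 did not pass (camera adjusted p = 8.06e-17, adjusted p = 0.142 with an estimated correlation), and 19 were higher adjusted over the list alone, with the sterol sensor Insig1 at 1.41 (SE 0.15) and the fatty acid elongase Elovl6 at 1.24 (SE 0.14). Of 25 transcripts of glycolysis and HIF1A targets, 16 rose and 9 did not pass (camera adjusted p = 1.39e-16, adjusted p = 0.0705 with an estimated correlation), and 18 were higher adjusted over the list alone, with Bnip3 at 2.26 (SE 0.30), Slc16a3 at 2.23 (SE 0.36) and Aldoc at 2.15 (SE 0.38). Of 20 ERK outputs, 12 rose and 8 did not pass (camera adjusted p = 1.45e-11, adjusted p = 0.136 with an estimated correlation), and 14 were higher and 1 lower adjusted over the list alone, with Ier3 at 2.17 (SE 0.24), Dusp6 at 2.01 (SE 0.28) and Spry4 at 1.89 (SE 0.23). Of 27 ATF4 and amino acid response genes, 8 rose and 19 did not pass (camera adjusted p = 1.88e-10, adjusted p = 0.326 with an estimated correlation), and 18 were higher adjusted over the list alone. The cystine transporter Slc7a11 of that list rose by 2.70 (SE 0.55, adjusted p = 0.0168), a call lost without 926 (0.0652). Of 25 proliferation genes, 2 rose and 23 did not pass (camera adjusted p = 5.65e-10, adjusted p = 0.504 with an estimated correlation), and 16 were higher adjusted over the list alone, with the mitotic activator Cdc20 at 1.21 (SE 0.22). The proliferation mean of the Pten line 952, 10.66, lay within the 10.47 to 11.09 of the Kras lines, unlike 9.34 in 926 and 9.84 in 928. Of 23 ribosome biogenesis genes, 2 rose and 21 did not pass (camera adjusted p = 2.37e-06, adjusted p = 0.504 with an estimated correlation), and 7 were higher adjusted over the list alone, although the list mean of 897 (10.42) lay below that of 952 (10.59), while Gnl3 had 0.59 (adjusted p = 0.053).

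Of 23 p53 target genes, 7 fell in the Kras lines and 16 did not pass (camera adjusted p = 0.00643, adjusted p = 0.142 with an estimated correlation), and 8 were lower adjusted over the list alone, with the TNF receptor Eda2r at -3.38 (SE 0.61) and Fas at -1.96 (SE 0.21). Of 18 fibroblast and stellate genes, 1 fell and 17 did not pass (camera adjusted p = 0.000206, adjusted p = 0.504 with an estimated correlation), and 9 were lower adjusted over the list alone. Postn had -4.76 (adjusted p = 0.0533) and Dcn -4.06 (adjusted p = 0.132). Among the Pten lines Postn lay at 12.8 in 926 and 13.3 in 928 but 6.63 in 952, where the Kras lines had 6.08 to 6.26, and Col1a1 at 12.6, 12.5 and 8.50. With 926 and 928 left out, the Pten side is 952 alone, which is assumed to vary like the lines of the other groups. The number of genes called was then 3919, of which 17.9% were higher in Kras lines, and camera then pointed up for p53 targets (adjusted p = 0.994), fibroblast genes (0.377) and mesenchymal genes (0.0165), while the proliferation call was lost (0.0704). Camera sets a list against the other genes, and the median log2 fold change over all genes in that fit was -0.141. The p53 target means of the Kras lines, 10.28 to 10.44, all lay below the 10.705 of 952. The p53 target call was lost without 928 alone (adjusted p = 0.145). With the proliferation mean as a covariate 412 genes were called. The calls of p53 targets (0.574), fibroblast genes (0.766) and ribosome biogenesis (0.0730) were lost. The call of proliferation itself was lost too (0.478), by construction, since that list's own mean is the covariate. Of 18 quasi-mesenchymal subtype genes, 5 rose, 1 fell and 12 did not pass (camera adjusted p = 0.00176, adjusted p = 0.0705 with an estimated correlation), and 6 were higher and 2 lower adjusted over the list alone. That call was lost without 952 (adjusted p = 0.0543). The epithelial, mesenchymal and ductal lists were not called (camera adjusted p = 0.277, 0.467 and 0.601), nor were the classical subtype (0.460), lysosome (0.164), interferon (0.610) and NRF2 (0.466) lists. Without 952 the mesenchymal list (0.000678) and the lysosome list (0.00447) were called down, the second also after renewed quantile normalization (0.00204). In the mTOR component list the median was 0.08 and the mean -0.05.

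The comparison of Pten with p53 lines asks how the PI3K/Akt route differs from the p53 model. The secretory proteins Wfdc2 and Spink4 were higher by 4.41 (SE 0.38, n = 3 and 4 lines, adjusted p = 0.000379) and 4.36 (SE 0.33, adjusted p = 0.000305), Gabrp by 5.14 (SE 0.67), Aadac by 4.30 (SE 0.46), Cdh17 by 4.03 (SE 0.44), Eda2r by 4.03 (SE 0.61) and Pzp by 3.95 (SE 0.73). Lower were Pcolce2, an enhancer of procollagen processing, at -3.47 (SE 0.39), the developmental regulator Eya1 at -2.92 (SE 0.28), the endopeptidase Mme at -2.90 (SE 0.49), Nrn1 at -2.86 (SE 0.46) and the amino acid transporter Slc38a4 at -2.65 (SE 0.41). Other large changes did not outlast the loss of a line. Mcpt2 (4.64) ended without 911 (0.0537), 961 (0.0569) or 926 (0.0907), Sfrp2 (-3.52) without 911 (0.0509), 926 (0.0859) or 952 (0.0738), Sema3d (-3.05) without 926 (0.0579) and Capn6 (-2.83) without 926 (0.0634). Dmbt1 (4.28) and Cyp2c65 (4.06) ended without 911, 961, 946F, 926 or 952, with adjusted p from 0.0537 to 0.115. Cdh10 (-2.80) ended without 911, 961, 946, 926, 928 or 952 (0.0536 to 0.107), and Gatm (-3.66) without any of 10 lines, 961 being the exception (0.0563 to 0.130). Cdkn2a fell by 1.89 (SE 0.47, adjusted p = 0.0384), a call lost without 911, 961, 946, 399, 403, 907, 928 or 952 (0.0512 to 0.0931), and Cdkn2b had -0.31 (adjusted p = 0.724). In all, 810 genes were higher and 753 lower, or 51.8% higher, against 32.4% once each array was centred on its median. All lines of 1 group lay above the other for 19.8% of the genes tested, which chance gives to 5.71%. The number called was 1029 without 911, 869 without 961, 1041 without 946F and 576 without 926.

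Of 25 sterol and fatty acid synthesis genes, 20 fell in the Pten lines against the p53 lines and 5 did not pass (camera adjusted p = 1.33e-21, adjusted p = 0.137 with an estimated correlation), and 23 were lower adjusted over the list alone. The isomerase Idi1 had -1.42 (SE 0.27), Elovl6 -1.36 (SE 0.14), Hsd17b7 -1.25 (SE 0.14) and the sterol demethylase Cyp51 -1.13 (SE 0.20). Of 25 proliferation genes, 7 fell and 18 did not pass (camera adjusted p = 1.03e-13, adjusted p = 0.330 with an estimated correlation), and 22 were lower adjusted over the list alone. The proliferation mean was 9.34 in 926 and 9.84 in 928, but 10.66 in 952, within the 10.65 to 11.17 of the p53 lines. The replication factor Mcm3 had -1.33 (SE 0.31), lost without 961, 946, 946F, 926 or 928 (0.0572 to 0.115). Of 23 ribosome biogenesis genes, 9 fell and 14 did not pass (camera adjusted p = 9.79e-12, adjusted p = 0.313 with an estimated correlation), and 16 were lower adjusted over the list alone, with Gnl3 at -0.79 (SE 0.16), lost without 926 (0.0821). Of 27 ATF4 and amino acid response genes, 10 fell and 17 did not pass (camera adjusted p = 1.01e-10, adjusted p = 0.313 with an estimated correlation), and 16 were lower adjusted over the list alone, while Cth had -1.82 (adjusted p = 0.0563). Of 23 p53 target genes, 13 rose and 10 did not pass (camera adjusted p = 5.82e-10), and 14 were higher and 1 lower adjusted over the list alone. Among them the RNA-binding protein Zmat3 rose by 1.82 (SE 0.17, adjusted p = 0.000664), the costimulator Cd80 by 3.38 (SE 0.52, with 1.55 from its other probe set) and Trp53inp1 by 1.62 (SE 0.28). Of 17 ductal genes, 6 rose and 11 did not pass (camera adjusted p = 0.000157, adjusted p = 0.137 with an estimated correlation), and 8 were higher adjusted over the list alone, with Prom1 at 3.28 (SE 0.54).

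Of 28 epithelial genes, 5 rose in the Pten lines against the p53 lines and 23 did not pass (camera adjusted p = 0.0195, adjusted p = 0.685 with an estimated correlation), and 5 were higher and 2 lower adjusted over the list alone, with Krt7 at 2.07 (SE 0.35). The mean of 946 (9.69) lay above that of 928 (9.59). The call was lost without 911 (0.0937), 961 (0.106) or 928 (0.0733). Of 20 classical subtype genes, 3 rose and 17 did not pass (camera adjusted p = 0.0387, adjusted p = 0.589 with an estimated correlation), and 5 were higher adjusted over the list alone, with the mucosal factor Tff3 at 3.44 (SE 0.64). This call was lost without 911 or 961 (0.108 each). Of 17 mesenchymal transition genes, 1 fell and 16 did not pass, also adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.603 with an estimated correlation), and the call was lost without 911 (0.0563) or 952 (0.692). Fibroblast and stellate genes were not called (camera adjusted p = 0.678), but without 952 their median was 0.65 with an adjusted p of 0.00374. Postn lay at 11.0 to 13.1 in the p53 lines, beside 12.8, 13.3 and 6.63 in the Pten lines 926, 928 and 952. With 926 and 928 left out, the Pten side is again 952 alone, the line with the narrow second array, and the other groups supply the spread. In that fit 4558 genes were called and 85.0% of them were higher in the Pten line, the fibroblast list was called lower (adjusted p = 5.09e-06) and the epithelial (0.478) and classical (0.138) calls were lost. With the proliferation mean as a covariate 138 genes were called, and the epithelial and classical calls (0.0831 each) were lost. The proliferation call was lost too (0.179), by construction, since that list's own mean is the covariate. The mesenchymal call was lost after renewed quantile normalization (0.0802) and among the upper 50% of genes (0.108). ERK output (camera adjusted p = 0.391), glycolysis (0.629), lysosome (0.392), interferon (0.963), NRF2 (0.963) and quasi-mesenchymal (0.281) lists were not called. ERK output was called down against the Tsc1 fl/+ lines alone (0.00221), lysosome genes with the proliferation covariate (0.0135) or without 926 and 928 (0.0181), and quasi-mesenchymal genes without 926 and 928 (0.0350). Fibroblast genes were called down with the proliferation covariate (9.18e-05). Median and mean differed in sign for ERK output (0.04 and -0.09) and for NRF2 targets (-0.02 and 0.16), and the glycolysis test pointed down with a median of 0.02 and a mean of 0.11.

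**Figure D3:**
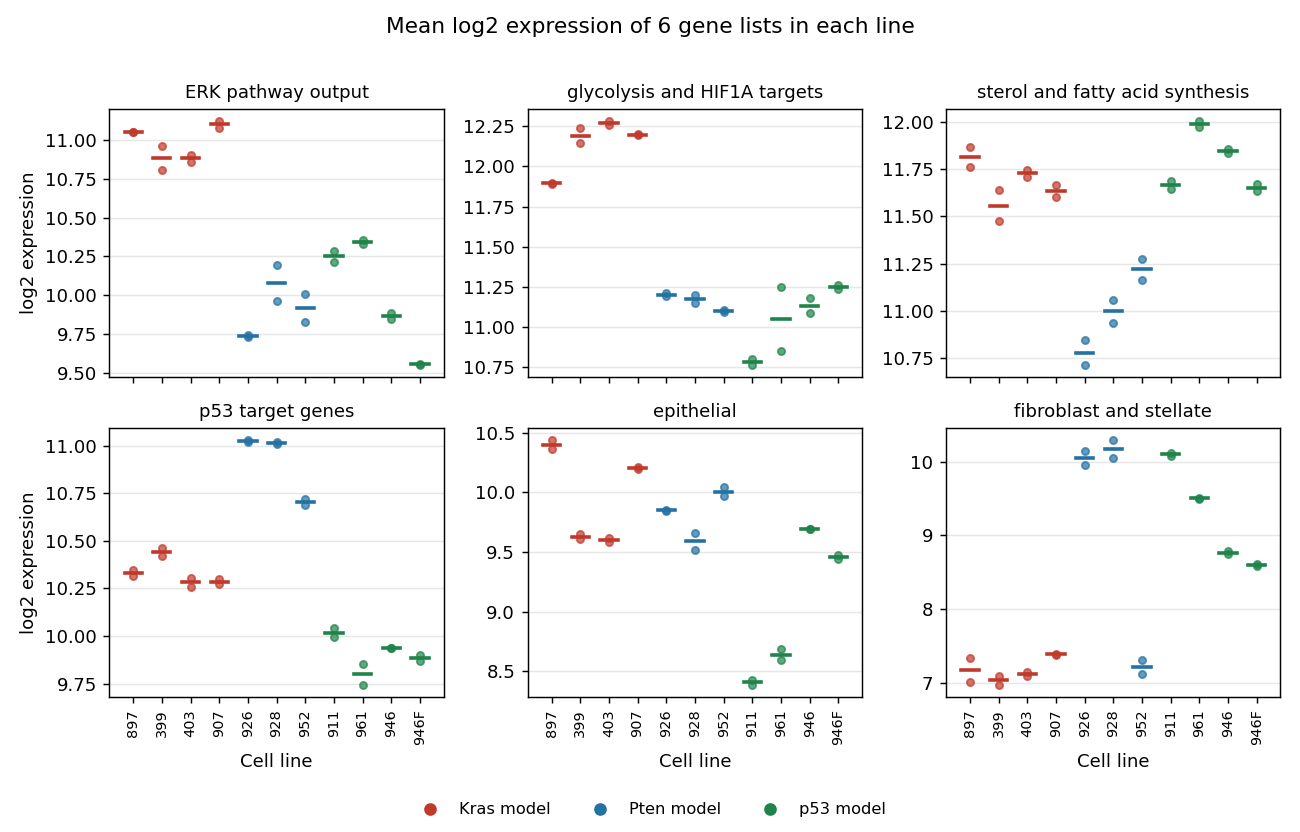
Mean log2 level of the measured members of 6 gene lists in the 11 lines, with points for arrays, bars for line means and colours for models. The fibroblast and stellate mean is 10.2 in 928 but 7.22 in 952, beside 7.04 to 7.39 in the Kras lines.

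The comparison within the p53 model asks how lines labelled Tsc1 fl/fl from acinar carcinoma differ from lines labelled Tsc1 fl/+ from normal pancreas. The protease cathepsin E, encoded by Ctse, was higher by 5.39 (SE 0.49, n = 2 and 2 lines, adjusted p = 0.00155), the cytochrome Cyp3a13 by 5.12 (SE 0.66), the mucin Muc1 by 4.84 (SE 0.42, adjusted p = 0.00119), Pls1, an actin bundler of microvilli, by 4.28 (SE 0.33) and the serpin Serpinb5 by 4.12 (SE 0.54). Pkhd1l1 was higher by 4.77 (SE 0.58) and Vsig1 by 4.69 (SE 0.57). The imprinted gene Dlk1 was lower at -2.67 (SE 0.32, adjusted p = 0.00435). The call of Cybb (4.50) was lost without 911 (0.103) or 946F (0.0819), that of Lgals2 (4.21) without 911 (0.109), 946 (0.111) or 946F (0.0752), and that of Lrrn1 (-3.98) without 911 (0.0783) and Igfbp5 (-2.96) without 911 (0.0704). Slc17a1 (3.84) lost its call without 403 or any p53 line (0.0502 to 0.135). Nexmif, Galnt18, Zim1, Bves, Eya4, Adcyap1r1 and Pdgfrl were lower, at -2.80 to -2.33. Bves lost its call without 911 (0.102), Eya4 without 911 (0.143) or 946F (0.0898) and Nexmif without 911, 961 or 946 (0.0828 to 0.162). The other 4 lost theirs without 946 and at least 1 Kras line, and in part without other lines, with adjusted p from 0.0524 to 0.231. In all, 313 genes were higher and 91 lower. Both lines of 1 genotype lay above both of the other for 44.3% of the genes tested, which chance gives to 33.3%. The lines 946 and 946F share a number, and whether they come from separate mice was not settled here, so n counts lines and not animals. The number called was 130 without 911, 252 without 961, 141 without 946 and 222 without 946F, where the lone line of a group is assumed to vary like the others. With 946 and 946F averaged into 1 line it was 112, and with a spread from the p53 lines alone 187.

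Of 28 epithelial genes, 7 rose in the lines labelled Tsc1 fl/fl and 21 did not pass (camera adjusted p = 2.67e-11, adjusted p = 0.0757 with an estimated correlation), and 14 were higher adjusted over the list alone. The keratin Krt19 rose by 2.38 (SE 0.31, adjusted p = 0.00642), lost without 946 (0.0515), and the epithelial regulator Elf3 by 2.77 (SE 0.46, adjusted p = 0.0173), lost without any of the 4 p53 lines 911, 961, 946 and 946F (0.0607 to 0.114). Of 22 lysosome and TFEB targets, 2 rose and 20 did not pass (camera adjusted p = 9.99e-08, adjusted p = 0.0757 with an estimated correlation), and 6 were higher adjusted over the list alone. The sialidase Neu1 rose by 1.17 (SE 0.20), lost without 911, 961, 946 or 946F (0.0848 to 0.107), and Fnip2, a partner of folliculin, by 1.01 (SE 0.15), lost without 961 (0.0756) or 946F (0.0734). Of 17 ductal genes, 3 rose and 14 did not pass (camera adjusted p = 0.000772, adjusted p = 0.0757 with an estimated correlation), and 6 were higher adjusted over the list alone. Of 20 classical subtype genes, 1 rose and 19 did not pass (camera adjusted p = 0.00165, adjusted p = 0.393 with an estimated correlation), and 2 were higher adjusted over the list alone. Of 20 ERK outputs, 1 fell and 19 did not pass (camera adjusted p = 2.62e-06, adjusted p = 0.0757 with an estimated correlation), and 5 were lower adjusted over the list alone, with Dusp4 at -1.12 (adjusted p = 0.0163), lost without 911 (0.110), 946 (0.108) or 946F (0.0617). Fibroblast and mesenchymal lists also pointed down (camera adjusted p = 0.00165 and 0.000851, adjusted p = 0.552 each with an estimated correlation), although none of their 18 and 17 members passed in limma.

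Several list calls within the p53 model rested on single lines and had no member that passed. The 25 glycolysis genes pointed up (camera adjusted p = 0.0123, adjusted p = 0.552 with an estimated correlation), a call lost without 911 (0.216) or 946F (0.113), after renewed quantile normalization (0.0526) and among the upper 50% of genes (0.0857), and Slc16a3 had 1.12 (adjusted p = 0.155). The 27 ATF4 genes pointed down (camera adjusted p = 0.0132, adjusted p = 0.740 with an estimated correlation), with 2 lower adjusted over the list alone, and this was lost without 911 (0.618) or 946F (0.315). NRF2 targets pointed up (camera adjusted p = 0.000772, adjusted p = 0.552 with an estimated correlation), lost without 961 (0.0594), with Gsta4 at 2.18 (adjusted p = 0.0847). The 22 interferon genes pointed down (camera adjusted p = 0.0251, adjusted p = 0.740 with an estimated correlation). That call was lost without 946 (0.209) or 952 (0.0635), among the upper 50% of genes (0.0636) and with arrays as independent replicates (0.0507), and without 961 the median was positive, at 0.10. The fibroblast call was lost without 911 (0.136). Not called were p53 targets (0.858), sterol synthesis (0.450), ribosome biogenesis (0.991), proliferation (0.456) and quasi-mesenchymal genes (0.456), of which Nt5e rose by 2.13 (adjusted p = 0.0261), lost without 911 (0.118), 961 (0.121) or 946 (0.162). Sterol genes were called down without 911 (0.00681) or 946 (0.0229) and proliferation genes up without 946F (0.0114). The p53 targets had a median of -0.11, a mean of 0.00 and a test that pointed up.

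The list nearest by name to the labels' common pathway, mTOR pathway components, holds transcripts of the pathway's own parts. The activity of mTOR was not measured. These components were called in no comparison by camera with all lines. Camera adjusted p was 0.141 for Kras against p53, 0.601 for Kras against Pten, 0.0726 for Pten against p53 and 0.420 within the p53 model. In Pten against p53 lines they were called down without 961 (0.0365), 926 (0.0367) or 928 (0.0180), with the proliferation covariate (0.00714) and without both 926 and 928 (0.00305). In Kras against Pten lines they were called up without 926 and 928 (0.0457). Of its 22 members, 1 rose and 3 fell in Kras against p53 lines, where the GTPase Rragd had -1.23 (SE 0.22) and Mlst8, a subunit of both mTOR complexes, -0.55 (SE 0.12). The kinase subunit Pik3cb fell by 1.04 (SE 0.18) and the translation repressor Eif4ebp1 by 0.72 (SE 0.14) in Pten against p53 lines, the second lost without 926 (0.0553). Within the p53 model Rragd had 0.80 (adjusted p = 0.0732). FOXO target genes were not called by camera with all lines in the 4 comparisons (adjusted p between 0.0857 and 0.418). They were called up in Kras against p53 lines without 911 (0.0318) and after renewed quantile normalization (0.0445), and in Pten against p53 lines after that normalization (0.0288). The self-contained test fry called them up in Kras against p53 (0.00568) and Pten against p53 lines (0.0373). Of 22 members, 8 rose and 2 fell in Kras against p53 lines, 10 and 2 adjusted over the list alone, among them Sesn3 at -1.31 (SE 0.13) and Erbb3 at 2.28 (SE 0.45). Lists for matrix proteases (0.265 to 0.721), acinar cells (0.624 to 0.991) and endocrine cells (0.0637 to 0.776) were not called with all lines either. The same held for endothelial cells (0.358 to 0.721), leukocytes (0.164 to 0.985) and Y-linked genes with Xist (0.392 to 0.991). The acinar mean was 6.79 in 928 to 7.14 in 952, with 6.89 in 946 and 6.91 in 946F. These means lay below every array median, so the acinar test compared low values. Y-linked genes and Xist moved in opposite directions across lines, so camera, which tests a shift in 1 direction, could hardly call that list. Leukocyte genes were called down in Kras against Pten lines without 928 (0.0122). Endocrine genes were called down within the p53 model without 911 (0.0218), 946F (0.0373) or 952 (0.0421), after median centring (0.04996) and with the p53 lines alone (0.0464). Single members passed in some, such as the adhesion protein Esam of the endothelial list, at 2.39 (SE 0.24, adjusted p = 0.00227) within the p53 model. Of all list calls with the preset correlation, the p53 targets of Pten against p53 lines held with an estimated correlation (adjusted p = 0.0106). With fry, calls were lost in Kras against p53 lines for lysosome (0.147), ribosome biogenesis (0.376), epithelial (0.0503), mesenchymal (0.0796) and fibroblast genes (0.0741). In Kras against Pten lines they were lost for ATF4 (0.0546), ribosome biogenesis (0.122), proliferation (0.120) and fibroblast genes (0.0902). In Pten against p53 lines they were lost for proliferation (0.0572), classical (0.0639), epithelial (0.155) and mesenchymal genes (0.412). Within the p53 model they were lost for classical genes (0.235), ATF4 (0.562) and interferon genes (0.679), and for glycolysis, NRF2, mesenchymal and fibroblast genes (0.379 each). The number of lists called, 10, 9 and 9 for the 3 comparisons of models, was matched or exceeded by 11, 21 and 22 of 35 divisions of the same lines, the real ones included.

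Differences among lines of a model, tested against the spread between duplicates, covered 6733 genes in the Kras model (33.8%), 10989 in the Pten model (55.1%) and 8181 in the p53 model (41.0%). These counts do not rank the models, because the spread was pooled over all lines. Duplicates of 952 and 926 lay furthest apart, with median absolute differences of 0.227 and 0.172 against 0.075 to 0.144 in the other lines. With the Pten arrays alone the Pten count was lower, as given below. The range reached a log2 value of 1 or more for 1405, 1572 and 2111 of them. Against the mean of the other 3 Kras lines, 897 had 4926 genes called, 399 had 4135, 403 had 2464 and 907 had 3169. In 897 the acyl-CoA synthetase Acsm3 was higher by 4.43 (SE 0.15, n = 2 arrays) and the collagen receptor Itga1 was lower at -4.37 (SE 0.13). In 399 the potassium channel Kcnma1 was higher by 4.46 (SE 0.22) and Ifi203 lower at -3.83 (SE 0.22). In 403 the opioid precursor Penk was higher by 4.45 (SE 0.17) and the inhibitor of metalloproteases Timp3 lower at -3.49 (SE 0.12). In 907 Cd34 was higher by 4.03 (SE 0.22), Fstl1 by 3.81 (SE 0.19) and the fibroblast list member Prrx1 by 3.79 (SE 0.15), and the annexin Anxa13 lower at -4.75 (SE 0.13). In that line 18 of 22 interferon genes, 20 of 25 proliferation genes and 13 of 17 mesenchymal genes were higher, and of 28 epithelial genes 13 were higher and 8 lower. In 897, 20 of 27 ATF4 genes were lower and 17 of 28 epithelial genes higher. In 399, 23 of 27 ATF4 genes were higher and 14 of 28 epithelial genes lower. Each of these lines is part of the other's reference mean, so the counts are not independent. In 403, 12 of 28 epithelial genes were lower as well and 4 higher.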

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

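The tests of other divisions of the lines and of random lists against a narrower range of values were planned, as were the fits that leave out 1 line, while the use of those fits to test the sterol pattern and the remaining tests below were chosen after the result was seen. Among 65 series of line or array values tested for 1 value far from the rest, 2 stood out. Chance gives such a value in about 1 in 20 series, so these 2 are no more than chance would give. Both belonged to the Kras line 907. Its mean over the interferon response list was 9.53, against 8.23 to 8.32 in the other Kras lines. Its mean over the matrix proteases and invasion list was 10.3, against 9.34 to 9.43 in the others.

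Chance is argued against, but not excluded, for the numbers of genes called between models. Of 35 divisions of the lines, 1, the real one, gave as many genes for Kras against p53 (2655, highest other 0), Kras against Pten (1659, highest other 107) and Pten against p53 (1563, highest other 79). The number of lists called is another matter, since chance cannot be excluded for it. As many lists came in 11 of 35 divisions for Kras against p53 (10, highest other 14), in 21 of 35 for Kras against Pten (9, highest other 15) and in 22 of 35 for Pten against p53 (9, highest other 15). Within the p53 model 3 divisions exist, too few for a share under 0.05, and the real one gave 404 genes and the highest other 4.

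Genes of sterol and fatty acid synthesis were lower in Pten than in p53 lines, with a median log2 fold change of -0.78. A single line or array as the whole cause is argued against by the medians without each Pten line or the second array of 952, the highest of which was -0.72 (-0.718). A narrower range of values on the Pten arrays is argued against by random lists matched on level, of which 0% of 10000 had a median as low, the lowest being -0.32. Slower growth, as read from the proliferation list, did not remove the difference, which had a median of -0.60 (-0.604) with that list's mean as a covariate. No biological explanation was tested, model and histology cannot be separated here, and the list call was lost with an estimated correlation.

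Fibroblast and stellate transcripts were abundant in the p53 lines and in the Pten lines 926 and 928, and low in 952 and the Kras lines. A common source of fibroblast RNA at different shares in 946 and 946F is argued against, because 3 list members were called lower in 946F and 4 higher, among them Dcn at -5.62 and Postn at 1.94. Fibroblasts among the cells of 926 and 928 may add these transcripts, and no value decides this. The epithelial mean of 926 and 928 lay -0.28 (-0.284) from that of 952, which either a share of fibroblasts or a state of the epithelial cells could give. The same question was not tested for 911 and 961, the whole Tsc1 fl/+ side of the p53 model. Their epithelial means were the lowest of all lines (8.41 and 8.64), beside fibroblast means of 10.1 and 9.50. Differences of epithelial and fibroblast genes from these lines therefore carry the same limit. The biological alternative, cells of these p53 and Pten lines that express matrix genes themselves, was not tested.

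Tsc1 transcript in the line labelled 946F stood above that of the line labelled 946 and of every fl/+ line. A swap of 946F with 911 or 961 would need a partner at the level of 946, and the lower of these lines lay 0.985 above it. This holds only if the probes read the deleted part of Tsc1, which was not checked, so a swap is not excluded. Probes outside the deleted part of Tsc1 would leave the level of 946F without bearing on its label. They would not by themselves part 946F from 946, which has the same label and was read by the same probe set. The position of the probes and a single wrong label stay open, since 946F lay 0.355 above the highest fl/+ line. No biological explanation was tested.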

How the results depend on the processing

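The fits with 952 from its first array, with the proliferation covariate and without 926 and 928 were chosen after the values were seen, as were all alternatives of the list tests other than estimated correlation, fry, the line as a random block, the upper 50% of genes and single lines left out. Gene counts for Kras against p53, Kras against Pten, Pten against p53 and within the p53 model were 2655, 1659, 1563 and 404. Over all alternatives, 197 counts and spread values stayed within 1.5 times of the main fit. Beyond that, 38 counts were lower, 14 counts were higher and 2 spread values moved. With all arrays and the line as a random block the gene counts were 4178, 3130, 3012 and 1314. Arrays as independent replicates gave 6034, 5276, 5563 and 2734, a construction that counts duplicates as lines. A replicate block with the line as a random block gave 4096, 3089, 2931 and 1259. Residuals of equal replicate number had a median correlation of 0.0105 over 55 pairs of lines (-0.508 to 0.368), with 14 over 0.1. The replicate numbers thus show no pairing common to all lines, while a pairing among some lines is not excluded. A minimum absolute log2 fold change of 1 left 770, 565, 418 and 269 genes by construction.

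Fits on the compared lines alone called 687 genes for Pten against p53 and 187 within the p53 model. Averaging 946 and 946F left 112. With the proliferation covariate the counts were 412 for Kras against Pten and 138 for Pten against p53, and 5 lists were called for Kras against Pten. Without 926 and 928, with 952 as the only Pten line, the gene counts were 3919 and 4558. Leaving out each line gave 1634 to 2929 for Kras against p53, 855 to 1561 for Kras against Pten, 576 to 1493 for Pten against p53 and 130 to 552 within the p53 model. The numbers of lists called ranged over 9 to 13, 9 to 10, 6 to 10 and 9 to 11 in those fits. With an estimated correlation they were 0, 0, 1 and 0, and fry called 5 for Kras against Pten and 4 within the p53 model. Of the named genes called, 49 of 64, 16 of 57, 11 of 59 and 7 of 28 kept the call in every alternative run on single genes, a minimum fold change aside, and 0 reversed.

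A minimum range of 1 left 1405 Kras, 1572 Pten and 2111 p53 genes that differed among lines, and a minimum change of 1 left 500 genes for 897, 353 for 399, 280 for 403 and 471 for 907. The Pten count was 5990 among the upper 50% of genes, where fewer were tested, and 4981 with its own arrays alone, against 10989. Among the upper 50% of genes the share of duplicates in the sum of squares was 3.12% and the median mean square between models 0.339. Without 926 and 928 the median over all genes of Kras against Pten was -0.141, and camera sets a list against the other genes. In that fit the test direction turned for p53 targets and fibroblast genes, whose medians stayed negative (-0.245 and -0.0874), and for mesenchymal genes (0.309). It turned for fibroblast genes of Pten against p53 without 952 (0.646, with -0.739 as the lowest median over lines left out). It also turned for interferon genes within the p53 model without 961 (0.103, lowest -1.23). The cause was not tested for these changes, apart from those that follow from construction. Signal over background limits genes near the floor of the arrays, and their differences are compressed.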

Other observations

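The division of the lines list by list, described last, was chosen after the results were seen, and the other values below are described without a test of an explanation. Transcripts of the sex chromosomes divided the lines across models. Eif2s3y and Uty of the Y chromosome were present in 897, 403, 926 and 928, where Eif2s3y had 8.58 to 9.43 and Uty 9.51 to 9.74, whereas Eif2s3y had 4.64 to 4.94 in the other lines. Xist, the RNA of the inactive X chromosome, had 6.14 to 6.43 in those 4 lines and 11.0 to 12.7 in the others, which include all p53 lines. Kdm5d, also on the Y chromosome, had 8.62 in 403, 8.73 in 926 and 9.13 in 928 but 5.75 in 897. The divide was uneven between models, and of 742 tested genes of the X chromosome limma called 94 in Kras against p53 (12.7%, against 13.3% of all genes), 48 in Kras against Pten (6.47%, against 8.32%), 52 in Pten against p53 (7.01%, against 7.84%) and 11 within the p53 model (1.48%, against 2.03%). X chromosome genes were thus called at no higher share than all genes, and 0 of 9 Y chromosome genes were called.

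The lines 946 and 946F share a number and a genotype label, and whether they come from separate mice was not settled here. By expression 1499 genes were higher and 1783 lower in 946F by limma against the spread of duplicates (n = 2 arrays each), 463 of them by a log2 value of 1 or more. Dcn had -5.62 (SE 0.16, adjusted p = 4.64e-13) and Postn 1.94 (SE 0.21, adjusted p = 4.5e-06). Col1a1 had 0.92 (SE 0.18), Col3a1 1.11 (SE 0.24), Pdgfrb 0.83 (SE 0.14) and Col1a2 -0.67 (SE 0.19). Cdkn2a was 10.95 in 946 and 10.05 in 946F.

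Taken list by list, the real division of the lines gave the largest difference of all 35 for 7 of 10 called lists in Kras against p53, 5 of 9 in Kras against Pten and 3 of 9 in Pten against p53, an exact p of 0.0286, which is the smallest the divisions can give. Uncalled lists reached it too, so that 8, 7 and 5 of the 24 lists did in all, among them Y-linked genes with Xist for Kras against p53 and for Pten against p53. These p-values were not adjusted over lists.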
